A study of Saccharomyces cerevisiae with 93 samples.

How the data were processed

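Libraries of the nascent and total chromatin of budding yeast were measured by strand-specific sequencing after micrococcal nuclease digestion. The 13 deposited tables hold coverage aligned to transcription starts, 1 line per gene, strand and library, made by the authors as signal in bins. The bin width of 20 bp was inferred from the number of bins against gene length, and every position in bp rests on it. The deposited signal is normalized coverage per bin, in whole multiples of 1 step per library and strand, with a mean near 1 over the genome. The deposited tables also carry annotation of each gene: replication time, distance to the nearest replication origin, class of promoter and polymerase occupancy. Upstream, the submitters' processing notes give CASAVA 1.7.0. The aligner, the genome build and the normalization factors are not given in the sources used here, so no coordinates are printed.

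Table entries were joined to the labels by table, strand letter and time. Of 93 samples 92 were matched. The total library with thiolutin at 16 min had no entry, and the 12 min entry of that table was not used here. In all 15 library entries matched no sample and were not used here. Library pairs with identical values numbered 7, all between the 2 chd1 courses, and were counted once, which left 85 libraries, of which 84 were used. The hir1 course 2 total at 0 min was left out because it was practically empty. Of 6326 genes 5 (YPR194C to YPR198W) were left out because their entries were shifted by 1 library in 2 tables, and 5695 of the remaining 6321 carried a symbol. Masked or missing bins made up 9.32% of the bins.

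Depth was read back from the step of each library and strand, accepted where values lay within 0.02 of whole multiples. It ran, as lowest, median and highest reads per bin, 12.2, 26.7 and 42.2 (wt 5 min pulse course 1 nascent), 34.4, 77.0 and 86.2 (its totals), 11.2, 16.4 and 68.5 (course 2), 44.0, 61.2 and 127 (20 min pulse course 1), 28.5, 47.1 and 71.0 (course 2), 19.1, 32.1 and 63.8 (thiolutin nascent), 39.5, 50.3 and 203 (thiolutin total), 72.9, 98.6 and 103 (synchronized nascent) and 63.6, 87.6 and 120 (synchronized total). For the mutants it ran 18.7, 39.3 and 60.5 (chd1), 14.2, 19.8 and 35.2 (hir1 course 1), 16.0, 36.8 and 105 (hir1 course 2) and 24.0, 40.4 and 68.8 (ioc3), with totals at 27.0 (chd1), 38.0, 70.1 and 105 (hir1 course 1), 0.0501, 39.9 and 81.1 (hir1 course 2) and 13.5 (ioc3).

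Every measure except the S phase share is a ratio or a correlation within a library, so the authors' scale per library cancels, which was tested on simulated data. Landmarks came from the mean profile of the 5 wt total libraries of course 1: the nucleosome-depleted region (NDR) at -90 bp, nucleosomes at 50, 210, 370, 530 and 710 bp and linkers at 130, 290, 450 and 630 bp. The NDR window was 50 bp to each side, nucleosome windows 30 bp and linker windows 15 bp. The NDR ratio is NDR signal over that of the gene body from the start to 800 bp. Phasing amplitude is the log2 ratio of nucleosome to linker signal. Positions are peaks within 60 bp of the landmark, and the repeat length is the slope over the nucleosomes. Array similarity is the correlation of a gene's bins with the wt total library before EdU. For single genes the NDR log2 ratio carried a pseudocount of 0.1 of the median body signal, and array similarity was used as Fisher z. Genes under 0.25 of the median body signal were filtered, with at least 3 NDR bins and 20 body bins required. Deleted genes were examined by gene-body coverage relative to the mean gene. The S phase share carried a pseudocount of 0.01 of the mean gene.

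The 20 comparisons of single genes were fitted with limma 3.58.1 (trend, moderated), with Benjamini-Hochberg adjusted p under 0.05 as the threshold and unadjusted p under 0.05 for comparison. The time point was a block in the nascent against total and the ioc3 comparisons, a linear covariate in the thiolutin, chd1 and hir1 comparisons, and course was a random block through duplicateCorrelation (statmod 1.5.0) for chd1 and hir1. Library measures were tested by exact sign-flip or permutation tests, with up to 100000 resamples and adjustment within each family. Lists were tested with fry and camera at the preset correlation of 0.01 and at an estimated one, adjusted over the 17 lists: core histones, HIR-regulated histones, ribosomal protein, ribosome biogenesis, glycolysis, galactose, phosphate, heat shock and stress, G1/S, G2/M, pheromone, meiosis, subtelomeric families, amino acid biosynthesis, proteasome, highly transcribed and silent genes. The highly transcribed list joins the ribosomal protein, glycolysis and core histone lists. The silent list joins the galactose, meiosis and subtelomeric lists. The lists, windows, tests and most alternatives were chosen before the data were examined. Named genes were the 5 with the largest change in each direction among those past the threshold with the same sign in every pair or course, the 3 largest members of each list, and CHD1, HIR1, IOC3 and the core histone genes. The text names those that serve each comparison. A gene that met this rule in the synchronized comparison is not reported here.

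The pairing of nascent and total libraries comes from the protocol, in which the total is an aliquot of the same culture. It was checked by correlating, across genes, the deviations of the nascent and the total library from the means of their groups. The correlations of NDR values ran from 0.0933 to 0.366 (wt, best with the own time in 4 of 4), 0.00187 to 0.130 (thiolutin, 1 of 3), -0.0222 to 0.0830 (hir1 course 1, 1 of 3), -0.0231 to 0.130 (hir1 course 2, 2 of 6) and 0.229 to 0.266 (synchronized, 3 of 3). For arrays they ran from 0.0947 to 0.230 (4 of 4), -0.0158 to 0.0729 (1 of 3), -0.0223 to 0.0578 (1 of 3), -0.0175 to 0.106 (2 of 6) and 0.0931 to 0.205 (3 of 3).

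On simulated data a change of size 1 in 200 genes was recovered for 0 genes in the wt NDR comparison (187 at size 2), 72 in hir1 course 2, 153 in ioc3 and 137 in the wt array comparison, with 0, 1, 5 and 8 false calls. Thiolutin against untreated NDR values recovered 0 at size 1 and 75 at size 2, and its arrays 93 at size 1. The wt NDR slopes recovered 0 at size 0.5 and 168 at size 1. The chd1 comparisons recovered 109 (NDR) and 184 (array) with 92 and 112 false calls, so the course block with 3 courses did not hold its rate of false calls. A raised proteasome list was found by fry in the wt NDR comparison (adjusted p = 0.00017) and not in the thiolutin one (adjusted p = 0.129). Alternatives covered the pseudocount, the NDR window, the gene filter, the landmarks, the reference, means against medians, the blocks, the controls and leaving out single libraries or courses. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 with the package data.table (version 1.17.8) were used.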

Results

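The libraries mapped nucleosomes on newly copied DNA in budding yeast. Wild-type cells (wt) and strains lacking CHD1, HIR1 or IOC3 took up EdU, a thymidine analogue, during a short pulse and were chased with thymidine for stated minutes. The synchronized wt course is an exception, since its labels give minutes after release and neither a pulse nor a chase. Crosslinked chromatin was digested with micrococcal nuclease, which spares DNA wrapped in nucleosomes. The EdU-carrying strands form the nascent libraries, and an aliquot taken before their capture forms the total library of the same culture. The labels describe 93 samples in 71 groups, and 85 distinct libraries were obtained from the tables, 60 nascent and 25 total. The wt courses with a 5 min pulse hold 4 nascent and 5 total libraries (course 1, chases of 4, 8, 12 and 16 min plus total chromatin before EdU) and 7 nascent libraries (course 2, 0 to 25 min). The wt courses with a 20 min pulse hold 7 and 6 nascent libraries. A wt course with thiolutin, an inhibitor of RNA polymerases, holds 4 nascent and 4 total libraries, and a course released synchronously into S phase holds 5 nascent and 3 total. The mutant courses hold 7 nascent libraries for chd1, 6 and 7 for hir1 courses 1 and 2 and 7 for ioc3. They come with 1 asynchronous total library for chd1, 4 and 7 total libraries for hir1 and 1 for ioc3. The titles of the 20 min pulse courses and of all mutant nascent courses call them input DNA, while their time point labels say nascent. The time point labels were followed, and every value of the pulse-length, 20 min pulse and mutant comparisons rests on that choice. The 7 nascent libraries given for a second chd1 course held values identical to those of the first, so they were counted once.

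Depth, read back from the steps in the coverage, ran from 11.2 to 126.5 reads per 20 bp bin over the 60 nascent libraries (median 40.1). The 25 total libraries ran from 0.0501 to 203.1 (median 58.4). The lowest, the hir1 course 2 total library at 0 min, was practically empty and was left out, and the 15 min total of that course had 3.67 reads per bin. The nascent libraries with thiolutin had 14.6 to 48.1% empty bins. Times of one course are serial samples of one culture, so the p-values below measure only the spread between these libraries.

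The deleted genes were examined first. CHD1 coverage, relative to the mean gene, was 0.0498 to 0.159 in the 8 chd1 libraries and 0.383 to 1.82 in the 76 others. IOC3 coverage was 0.0593 to 0.221 in the 8 ioc3 libraries against 0.774 to 5.69 in the 76 others. HIR1 coverage had a median of 0 over the 23 libraries labelled hir1, and 1.05 to 2.30 in the 61 others. Some coverage of the deleted gene was thus left in the chd1 libraries (median 0.122 against 0.997 in the others) and in the ioc3 libraries. For IOC3 it was highest in the total library (0.221), against 0.0593 to 0.105 in the ioc3 nascent libraries and a median of 1.37 in the others. In 4 hir1 libraries HIR1 stood above the other hir1 libraries, which reached at most 0.0503. The libraries labelled hir1 course 1 total carried HIR1 at 0.243, 0.130, 0.170 and 0.524 at 2, 8, 15 and 25 min.

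The first question was how the nucleosome arrays of newly copied genes differ from those of bulk chromatin. Array similarity, the median over genes of the correlation of a gene's profile with that of wt total chromatin before EdU, was lower in nascent than in total chromatin in 19 of 19 pairs matched by label and time. The means were 0.564 and 0.756, a difference of -0.192 ± 0.134 (SD, n = 19), with p = 3.8e-06 in an exact sign-flip permutation test, the smallest that test can give. The 3 pairs of hir1 course 1 are not shown to be of 1 culture, since their total libraries carry HIR1, and without them the difference was -0.188 (exact permutation p = 3.05e-05). The nucleosome-depleted region (NDR) upstream of the start held more signal in nascent chromatin than the 0.429 of the gene-body level in total chromatin, higher in 15 of 19 pairs (difference 0.0374 ± 0.0316, adjusted exact permutation p = 0.000372, and 0.0292 at an adjusted p of 0.101 with the median over genes). The +1 nucleosome, the first downstream of the transcription start, lay at 53.4 bp in nascent and 59.1 bp in total chromatin, nearer the start in 14 of 19 pairs (difference -5.66 ± 6.93 bp, adjusted exact permutation p = 0.00278). The repeat length was 165.1 bp against 163.5 bp, longer in 14 of 18 pairs (1.63 ± 1.73 bp, adjusted exact permutation p = 0.00195). As a slope over the peak positions, +1 among them, the repeat is not independent of the +1 shift. The repeat difference was 0.693 bp without hir1 course 2 (exact permutation p = 0.0747) and 0.999 bp with the median over genes (adjusted exact permutation p = 0.0739). Phasing amplitude, the log2 ratio of nucleosome to linker signal, was 0.311 against 0.260, higher in 14 of 19 pairs (0.0514 ± 0.101, adjusted exact permutation p = 0.0392). The amplitude difference was 0.0184 without hir1 course 1 (exact permutation p = 0.310), 0.0460 without thiolutin (exact permutation p = 0.107) and 0.0538 without the synchronized course (exact permutation p = 0.0693).

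**Figure D1:**
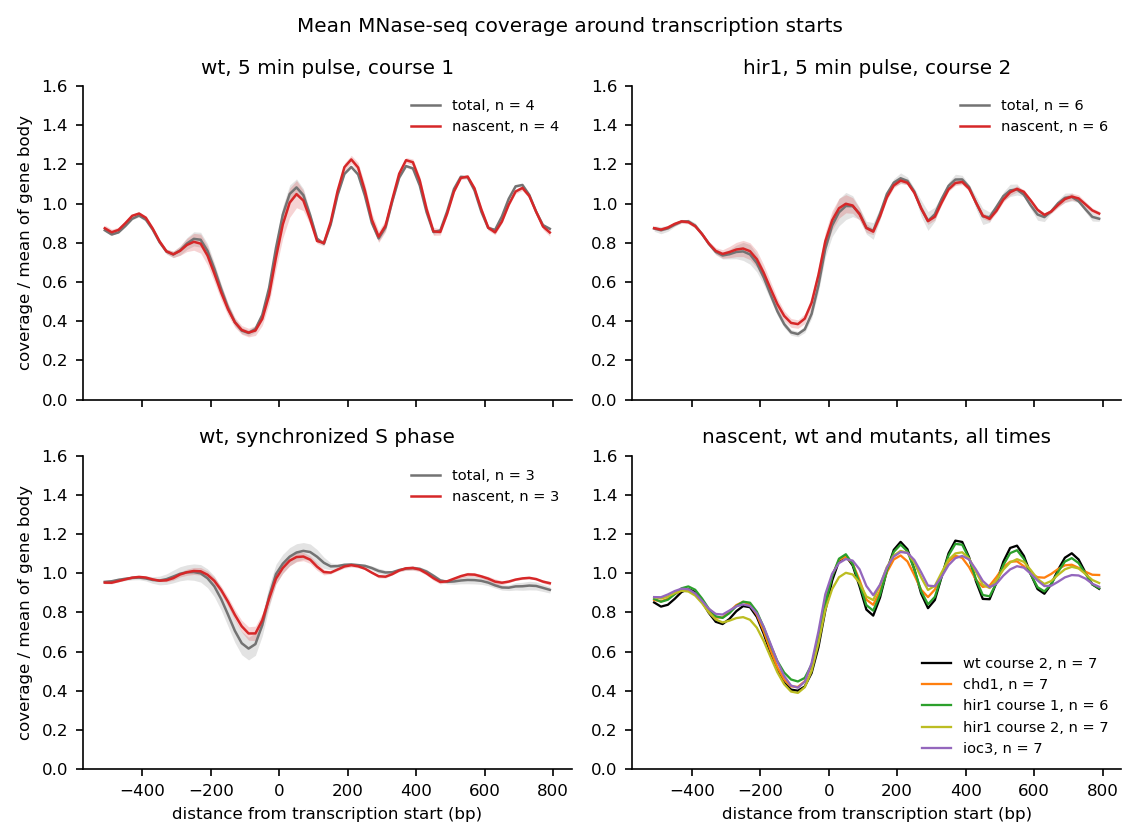
Mean MNase-seq coverage against distance from the transcription start (bp), each library divided by its mean from the start to 800 bp, with bands of 1 SD for nascent (red) and total (grey) libraries of the same times. The dip upstream of the start is the NDR, the peaks are nucleosomes, and the lower right panel shows the lower nucleosome peaks of chd1, hir1 course 2 and ioc3 nascent chromatin against wt course 2.

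Within courses the picture varied. In wt course 1 array similarity was 0.684 in nascent and 0.845 in total libraries (difference -0.161 ± 0.0630, lower in 4 of 4 pairs), while the NDR ratio differed by only -0.00477 and the +1 nucleosome lay 2.60 ± 2.36 bp further downstream (4 of 4). That +1 difference was 6.12 bp at 12 min and 1.00 to 1.66 bp at the other times. With thiolutin the similarity difference was -0.369 ± 0.173 (3 of 3 lower), but corrected for strand noise it was -0.0950 against -0.105 in wt (exact permutation p = 0.771 for their difference). Uncorrected, in the libraries labelled hir1 course 1 it was -0.210 and in the synchronized course it was -0.0453 ± 0.0255 (3 of 3 lower). The synchronized course showed little phasing, with a mean amplitude of 0.0492 (nascent) and 0.0212 (total) against 0.448 and 0.431 in wt course 1. Some nucleosome peaks were not found in its totals at 32 and 40 min, so its peak positions are poorly defined. Exact tests of 4 or 3 pairs are too small to pass the threshold. In hir1 course 2 the NDR ratio was higher by 0.0506 ± 0.0178, the repeat longer by 3.51 bp, the +1 nucleosome nearer the start (-8.15 bp) and the similarity lower (-0.187), each in 6 of 6 pairs (adjusted exact permutation p = 0.0391).

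**Figure D2:**
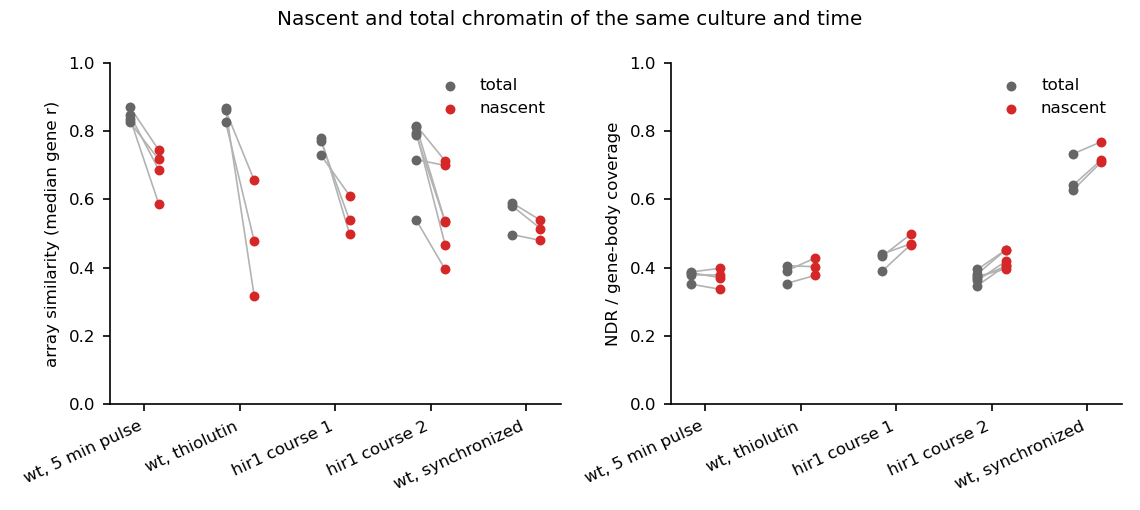
Array similarity (left, median correlation over genes) and NDR signal relative to the gene body (right) of total (grey) and nascent (red) libraries of 1 labelled course and time, joined by lines, for 19 pairs in 5 courses. Every nascent point on the left lies below its total, and on the right 15 of 19 nascent points lie above.

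At single promoters of wt cells, EMI1, which is needed for early meiotic induction, carried more NDR signal in nascent than in total chromatin by 2.23 ± 0.30 (log2, SE, higher in 4 of 4 pairs, limma adjusted p = 0.00018). GRX2, a glutaredoxin, rose by 1.92 ± 0.28, the small heat shock protein gene HSP42 by 1.64 ± 0.30, the trehalose synthase subunit gene TSL1 by 1.57 ± 0.29 and URB2, of ribosome biogenesis, by 1.56 ± 0.23. IES6, a subunit of the INO80 remodeller, was lower by -2.30 ± 0.30 (0 of 4 pairs higher, limma adjusted p = 0.00018), as were the riboflavin gene RIB7 (-1.76 ± 0.30), DAP1 (-1.63 ± 0.27), the cell wall gene TIP1 (-1.59 ± 0.28) and the mitochondrial NAD carrier gene YIA6 (-1.53 ± 0.28). Of 5368 genes, 105 were higher and 240 lower at an adjusted p under 0.05, and the median of all genes was -0.12. The NDR ratio of the gene-averaged profiles of these pairs differed by only -0.0048. Among 125 measured ribosomal protein genes 11 were higher and 2 lower (12 and 2 adjusted over the list alone), with RPS31 at 1.34 ± 0.29, RPS25B at 1.30 ± 0.29 and RPS23A at 1.26 ± 0.29. Against other genes camera, a set test, gave this list an adjusted p of 0.00072 with its preset correlation, lost with an estimated correlation (adjusted p = 0.45). Of 8 core histone genes 2 were lower (4 adjusted over the list alone), HTA2 by -1.0 ± 0.28 and HHF2 by -0.95 ± 0.28, reads of paired histone genes being possibly shared between copies. For the 6 HIR-regulated histone genes 1 was lower, also when adjusted over the list alone. HIR1 itself was at -0.85 ± 0.30 (limma adjusted p = 0.087).

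The other lists of that comparison gave few calls each. Highly transcribed genes join the ribosomal protein, glycolysis and core histone lists, and silent genes the galactose, meiosis and subtelomeric lists. Counts of these joined lists over all genes repeat the calls of their parts and are not separate results. The deposited polymerase occupancy had a Spearman rho of 0.0360 with the NDR difference (5187 genes). Among 30 heat shock and stress genes 3 were higher and 2 lower (4 and 3 adjusted over the list alone), the lower including the Hsp40 gene SIS1 (-1.51 ± 0.28). Of 87 ribosome biogenesis genes 1 was higher, NOP9 (1.30 ± 0.24), and 1 lower, the fibrillarin gene NOP1 (-1.12 ± 0.24), the same counts adjusted over the list alone. Of 17 glycolysis genes 0 were higher and 1 lower (1 and 1 adjusted over the list alone), TDH1 (-1.24 ± 0.27), a member of the TDH family whose reads may be shared between copies. Of 35 proteasome genes 1 was higher and 2 lower (2 and 3 adjusted over the list alone), with PRE1 at 0.96 ± 0.28 and PRE2 at -1.20 ± 0.26. G1/S genes gave 1 higher of 35, the cell cycle transcription factor gene SWI4 (1.06 ± 0.28), and pheromone genes 1 higher, the receptor gene STE2 (1.06 ± 0.30), and 1 lower, the kinase gene FUS3 (-1.26 ± 0.32), of 26, unchanged when adjusted over the list alone. G2/M genes gave 1 lower of 18, meiosis genes 1 higher and 2 lower of 43, and galactose and phosphate genes 0 of 7 and 0 of 15, the same adjusted over the list alone (limma, with 1225 of all genes at an unadjusted p under 0.05). Amino acid biosynthesis genes gave 3 lower of 62 (2 adjusted over the list alone), subtelomeric families 1 lower of 18 (0), silent genes 1 higher and 3 lower of 68 (1 and 2) and highly transcribed genes 11 higher and 5 lower of 150 (14 and 5), the last with a camera adjusted p of 0.0056, lost with an estimated correlation (adjusted p = 0.45). The call count rested on the later times, being 27 without the 16 min pair and 108 without the 12 min pair, and it was 63 without the pairing, 165 without the gene filter and 534 with a pseudocount of 0.5.

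Arrays of single genes in wt cells were mostly less like the reference in nascent chromatin. Array similarity, as Fisher z, was lower in 2264 of 5373 genes and higher in 28 (median of all genes -0.40). The lowest values were those of YEL045C (-1.97 ± 0.21, limma adjusted p = 8.2e-07), the flavin monooxygenase gene FMO1 (-1.72 ± 0.16), COX14, of cytochrome oxidase assembly (-1.69 ± 0.21), GPI13 (-1.67 ± 0.19) and the decapping gene EDC1 (-1.64 ± 0.22), each lower in 4 of 4 pairs. Ribosomal protein genes had 50 lower and 2 higher of 125 (the same adjusted over the list alone), among them RPL22A (-1.21 ± 0.19) and RPL19A (-1.16 ± 0.17). Glycolysis genes had 12 lower of 17, among them PGK1 (-1.27 ± 0.18) and GPM1 (-1.09 ± 0.17), proteasome genes 22 of 35, among them PRE4 (-0.95 ± 0.17), and amino acid biosynthesis genes 31 of 62, among them HIS3 (-1.15 ± 0.22). Adjusted over the list alone the counts were 12, 23 and 32. The thymidylate synthase gene CDC21, of the G1/S list, was at -1.0 ± 0.16. No list stood apart from the other genes in camera. The genes called higher did not keep their sign against a second reference, made of the very totals compared here. YCR064C (0.78), the inositol synthase gene INO1 (0.77), YBL028C (0.75), LSB1 (0.71) and FRM2 (0.71) turned to -1.11, -0.95, -1.06, -0.93 and -0.74 against the mean of the 4 to 16 min total libraries. Without the 16 min pair 1461 genes were called, with library depth as a covariate 313, and 5272 against the mean of the total libraries. Each total compared here is part of that mean and so resembles it by construction. Neither the turned signs nor the 5272 calls are therefore an independent check.

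With thiolutin, 36 promoters were lower and 1 higher in nascent chromatin (of 5376 genes, with a median of -0.21). The NDR ratio of the gene-averaged profiles went the other way, with a mean difference of 0.0198, and turned negative with the median over genes. It was higher in nascent chromatin at 6 and 25 min and lower at 8 min. Empty bins made up 14.6 to 48.1% of the nascent libraries, and depth was not a covariate in any NDR fit. Few or no calls were left under other settings (limma), with 0 at a pseudocount of 0.5, without the gene filter or without the pairing (591, 497 and 619 genes with an unadjusted p under 0.05) and 2 with a fixed NDR window. The DnaJ-type chaperone gene MDJ2 was lower by -2.38 ± 0.52 (log2, SE, 3 of 3 pairs, limma adjusted p = 0.0094), IRC22 by -2.17 ± 0.52, the eisosome gene SUR7 by -2.12 ± 0.48, the ribosome biogenesis gene RLP24 by -1.53 ± 0.35 and YOR013W and YKL202W each by -2.57, while ECM18 was higher by 2.01 ± 0.50. Core histone genes, with a median of -0.55, moved down on balance against no change (fry adjusted p = 0.0192) and camera did not set them below other genes, with 0 of 8 called (2 lower adjusted over the list alone). HTB2, which may share reads with its pair HTB1, was at -1.93 ± 0.60 (limma adjusted p = 0.15). Array similarity was lower in 3268 of 5378 genes and higher in 1, YCR087C-A, whose 0.45 turned to -0.92 against the other reference. The lowest were YKL153W (-2.14 ± 0.27), HAB1 (-2.13 ± 0.33), INN1, of cytokinesis (-2.06 ± 0.34), IAH1 (-2.03 ± 0.32) and YFL012W (-2.01 ± 0.33), and RPL15A stood at -1.58 ± 0.26. With depth as a covariate 1495 genes were lower, and the strands of the nascent libraries agreed poorly (0.0835, 0.233 and 0.512 in the 3 pairs against 0.883, 0.822 and 0.885 in total). The NDR calls were 6 without the 8 min pair and 62 without the 6 min pair, and the array calls 1345 and 2062.

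In the libraries labelled hir1 course 1, 461 of 5368 promoters were higher and 76 lower in nascent chromatin (median of all genes 0.18). ERT1, a regulator of gluconeogenesis, was higher by 2.12 ± 0.24 (log2, SE, 3 of 3 pairs, limma adjusted p = 2.7e-06), SYG1 by 1.76 ± 0.26, YIL046W-A by 1.75 ± 0.22, TDA7 by 1.73 ± 0.30 and the Golgi GDP-mannose transporter gene VRG4 by 1.7 ± 0.27. IML1 was lower (-1.70 ± 0.26), with the mitochondrial superoxide dismutase gene SOD2 (-1.48 ± 0.28), the dynein gene DYN1 (-1.44 ± 0.24), RHO4 (-1.43 ± 0.24) and YPT11 (-1.37 ± 0.28). Amino acid biosynthesis genes gave 13 higher and 1 lower of 62 (14 and 2 adjusted over the list alone), among them ASN2 (1.04 ± 0.25). Glycolysis genes gave 4 higher and 1 lower of 17, the same adjusted over the list alone, with PFK2 at 1.52 ± 0.27. The 8 core histone genes had a median of -0.50 with 1 lower (4 adjusted over the list alone), HHT1 at -0.86 ± 0.26 with reads possibly shared with HHT2, and camera set them below other genes (adjusted p = 0.00024, and 0.33 with an estimated correlation). Arrays were less similar at 1662 of 5373 genes and more at 20, but at 16 and 2 with depth as a covariate. The nascent libraries were shallower (median 19.8 against 70.1 reads per bin). With 3 pairs depth runs largely along the nascent and total difference, so this fit cannot separate them. GAT3 (-1.83 ± 0.21), LMO1 (-1.62 ± 0.21), APQ12 (-1.50 ± 0.22), BAS1, a regulator of histidine and purine genes (-1.48 ± 0.23), IOC2, of the Isw1b remodeller (-1.47 ± 0.19), and PGI1 of glycolysis (-1.38 ± 0.20) were lower. YGL108C (0.94 ± 0.26), APL6 (0.84 ± 0.21), DYN1 (0.83 ± 0.20), SWS2 (0.82 ± 0.21) and DNM1 (0.70 ± 0.20) were higher. Each pair mattered, since the NDR calls were 0, 172 and 341 without the 25, 15 and 2 min pairs (limma) and 238 without the gene filter, and the array calls 0 without the 2 min pair and 733 without the 15 min pair.

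In hir1 course 2, 174 of 5343 promoters were higher and 19 lower in nascent chromatin. The kinase gene RCK1 (1.76 ± 0.28, log2, SE, 6 of 6 pairs, limma adjusted p = 0.0052), the deacetylase gene HOS1 (1.69 ± 0.28), ATG10 of autophagy (1.64 ± 0.30), the phosphatase gene PTC2 (1.63 ± 0.25) and BSC1 (1.62 ± 0.24) were higher. YLR257W (-1.37 ± 0.25), the pheromone pathway scaffold gene STE5 (-1.28 ± 0.35), YNL105W (-1.21 ± 0.25), IST2 (-1.20 ± 0.33) and MDY2 (-1.19 ± 0.26) were lower. PDC1 of glycolysis and HOM2 of threonine synthesis were each at 1.13, with SEs of 0.25 and 0.27. Silent genes (3 higher of 68, 5 adjusted over the list alone) and proteasome genes (1 of 35, 2 adjusted over the list alone) moved up on balance (fry adjusted p = 0.0034 for both), in a course whose median gene was at 0.18. Arrays were less similar at 1578 of 5348 genes, lowest at VHR1 (-1.56 ± 0.18), EDC1 (-1.48 ± 0.19), VAB2 (-1.37 ± 0.16), SNX3 (-1.33 ± 0.21), YEL009C-A (-1.32 ± 0.20) and the exosome gene RRP6 (-1.17 ± 0.18). The genes called more similar were 4, of which CCM1 was at 0.53 ± 0.17, while CIN2 (0.55) and FAA1 (0.32) turned to -0.029 and -0.86 against the other reference. NDR calls were 7, 22, 64 and 294 without the 6, 8, 25 and 15 min pairs, 37 without the gene filter and 476 with a pseudocount of 0.5. Array calls were 736, 803 and 827 without the 6, 8 and 25 min pairs, 1048 without the pairing and 2430 with depth as a covariate.

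In synchronized cells, of 87 measured promoters of ribosome biogenesis genes 36 were higher in nascent than in total chromatin and 0 lower (42 and 0 adjusted over the list alone), among them NUG1 (1.01 ± 0.16), UTP21 (0.97 ± 0.19) and UTP14 (0.95 ± 0.18). The list median was 0.37 against 0.16 for all genes, with a camera adjusted p of 9.5e-05, lost with an estimated correlation (adjusted p = 0.67). Ribosomal protein genes gave 24 higher and 9 lower of 126 (27 and 12 adjusted over the list alone), with RPS31 at 1.05 ± 0.17, and proteasome genes 10 higher and 1 lower of 35 (13 and 1 adjusted over the list alone). Over 5391 genes 1031 were higher and 149 lower. The NDR of this course was shallow, with a mean ratio of 0.730 (nascent) and 0.667 (total) against 0.371 and 0.373 in wt course 1. YKL202W led (1.85 ± 0.15, log2, SE, 3 of 3 pairs, limma adjusted p = 3.6e-19), followed by the translocon gene SSS1 (1.44 ± 0.16), ERT1 (1.43 ± 0.17), the chaperone gene SSE2 (1.32 ± 0.18) and TBS1 (1.29 ± 0.17). SWD2, shared by the COMPASS methyltransferase and the cleavage factor (-1.21 ± 0.15), DYN2 (-1.07 ± 0.16), AAD10 (-0.88 ± 0.15, a family whose reads may be shared between copies) and AHT1 (-0.87 ± 0.17) were lower. The histone chaperone gene ASF1 was at 0.94 ± 0.15, the PCNA gene POL30 at 0.61 ± 0.17 and the cyclin gene CLB3 at 0.73 ± 0.17. Array similarity changed at 33 of 5396 genes, up at BUD13 (0.97 ± 0.12), DPI8 (0.60 ± 0.09) and HXT4 (0.92 ± 0.12, with reads possibly shared within the HXT family). It fell at 30, lowest at YKL202W (-1.59 ± 0.14), the aquaporin gene AQY2 (-1.36 ± 0.17), RNT1 (-1.16 ± 0.13), SER3 (-1.15 ± 0.12) and FPR4 (-1.12 ± 0.11). NDR calls were 510 and 706 without the 40 and 55 min pairs and 373 without the pairing. Array calls were 16 with 40 bp bins, 15 without the pairing, 0 with depth as a covariate, 94 without the 32 min pair and 0 without either of the others (limma, 1139 genes with an unadjusted p under 0.05 over all pairs).

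The synchronized course also showed which genes had been copied. The share of signal in nascent over total chromatin ran opposite to a fitted replication time in the deposited annotation. Spearman's rho was -0.80, -0.73 and -0.67 at 32, 40 and 55 min across 6181 genes, which are not independent replicates. Another replication time in that annotation gave -0.687, -0.635 and -0.602. Whether the fitted time, which also sets the bins below, was derived from this course is not known here, so its agreement may be built in. In the earliest of 5 bins of genes the median log2 ratio was 0.67 at 32 min, 0.37 at 40 min and 0.27 at 55 min, and in the latest bin -1.27, -1.04 and -0.31. At 32 min the hexose transporter gene HXT3 (1.54, with reads possibly shared within the HXT family) and the iron reductase gene FRE3 (1.31) were high, and the chaperonin gene CCT6 (-2.51), MET32 (-2.38) and GET3 (-2.36) low. At 40 min AIM34 stood at 1.21 and GPN2 and the proteasome gene RPN8 at -3.13 and -2.96. At 55 min the proton pump gene PMA1 (0.90) and BRP1 (1.07) were high and MCA1 (-1.04) low. There was 1 library per time, so these values have no replicate check.

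**Figure D3:**
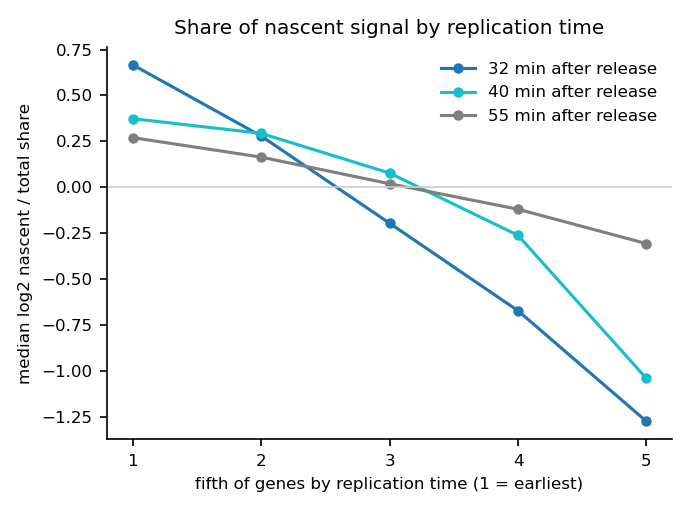
Median log2 ratio of a gene's share of nascent over total signal, for genes in 5 bins of replication time, at 32, 40 and 55 min after release. The line falls from 0.67 to -1.27 at 32 min and from 0.27 to -0.31 at 55 min.

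Change over the minutes after replication was examined next, to follow the maturation of nascent chromatin. At single genes of the 11 wt nascent libraries no slope passed the test, with 0 of 5367 promoters and 0 of 5372 arrays (limma, 437 and 290 with an unadjusted p under 0.05). The core histone promoters had a median slope of 0.25 log2 per 10 min against -0.08 for all genes, with 0 called (1 higher adjusted over the list alone) and a camera adjusted p of 0.012, lost with an estimated correlation (adjusted p = 0.14). HTA2 was at 0.72 ± 0.22 per 10 min, possibly sharing reads with HTA1, the proteasome gene SCL1 at -0.80 ± 0.19 and the histidine gene HIS7 at -0.82 ± 0.24, with limma adjusted p of 0.34, 0.14 and 0.28. For arrays RPP2B was at -0.56 ± 0.13 and TPI1 at -0.35 ± 0.12, with limma adjusted p of 0.77 and 0.89. At the level of libraries 35 relations with time were computed and none passed the adjustment. The wt 20 min pulse course 1 had an array similarity of 0.516 at its first and 0.707 at its last time (Pearson r = 0.940, exact permutation p = 0.00218, adjusted p = 0.0764, Spearman rho = 0.964, exact permutation p = 0.00278, n = 7, and r = 0.897 without the 0 and 22 min libraries). Its NDR ratio went from 0.584 to 0.439 (r = -0.873, exact permutation p = 0.0135, adjusted p = 0.211, rho = -0.857, exact permutation p = 0.0238, and r = -0.803 without those libraries). In its replicate, 20 min pulse course 2, array similarity went from 0.659 to 0.622 (r = -0.207, exact permutation p = 0.575, rho = -0.771, exact permutation p = 0.103, n = 6) and the NDR ratio from 0.465 to 0.458 (r = 0.0454, exact permutation p = 0.869). Phasing amplitude was higher at the last than at the first time in both, 0.235 against 0.111 (course 1) and 0.233 against 0.146 (course 2). Its slope was also positive in wt 5 min pulse course 2 and the mutant courses (0.00223 to 0.0224 per 10 min), none past the adjustment. In the wt 5 min pulse course 2 array similarity started at 0.615 and changed by -0.0396 per 10 min (r = -0.718, exact permutation p = 0.0653, adjusted p = 0.326, rho = -0.857, exact permutation p = 0.0238, and r = -0.860 without the 15 and 25 min libraries). Corrected for strand noise its slope was -0.00547 per 10 min, the strand agreement going from 0.757 to 0.424 and the depth from 39.8 to 16.0 reads per bin between the first and last time.

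The wt libraries of 0 to 8 min differed between the courses of a 20 min EdU pulse with 10 min in thymidine and those of a 5 min pulse with 5 min in thymidine. The 9 libraries of the 20 min pulse had a phasing amplitude of 0.176 ± 0.0424 against 0.439 ± 0.0445 (SD) in the 7 libraries of the 5 min pulse, all 9 below all 7 (difference -0.263, exact permutation p = 8.7e-05, the smallest that test can give). The NDR ratio was 0.508 against 0.419, with 8 of 9 above all 7 (adjusted exact permutation p = 0.00284), the repeat 166.9 against 165.2 bp (8 of 9, adjusted exact permutation p = 0.00109) and the +1 nucleosome at 53.6 against 47.8 bp (9 of 9, adjusted exact permutation p = 0.00146). Without 5 min course 2 the +1 difference was 3.56 bp (exact permutation p = 0.127) and the NDR difference 0.124 (exact permutation p = 0.0545). Array similarity differed by -0.00629 (exact permutation p = 0.861), and by 0.0357 and 0.0207 without 20 min course 1 and without 5 min course 1. By course, over 0 to 8 min, the amplitude was 0.171 and 0.181 (20 min) and 0.468 and 0.428 (5 min). The permutation treats serial libraries of 4 courses as replicates, and 2 courses against 2 are too few for an exact test to pass. Pulse and thymidine step differ together, so neither can be named as the source.

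Thiolutin asks whether nascent arrays depend on transcription. Against untreated course 1, 121 of 5368 genes had a lower and 1 a higher array similarity in nascent chromatin (median of all genes -0.36). Corrected for strand noise, the library means ran the other way, 0.818 with thiolutin and 0.795 without, at a strand agreement of 0.261 against 0.670. The ribosomal protein gene RPL15A stood at -1.35 ± 0.25 (Fisher z, SE, lower at both matched times, limma adjusted p = 0.032), with RPS20 at -1.05 ± 0.27 and RPL17A at -1.04 ± 0.28. YLR400W (-1.44 ± 0.30), the ATP synthase gene ATP20 (-1.39 ± 0.28), YMR090W (-1.36 ± 0.24), the mitochondrial ribosome gene MRPL37 (-1.36 ± 0.32) and PRM5 of the pheromone list (-1.18 ± 0.26) were lower, and TAF9, shared by TFIID and SAGA, was higher (0.82 ± 0.19). Of 124 ribosomal protein genes 3 were lower (5 adjusted over the list alone) and of 35 G1/S genes 1 (8 adjusted over the list alone), and camera set no list apart. At promoters 0 of 5366 genes passed (limma, 382 with an unadjusted p under 0.05), with ASF2 at 2.12 ± 0.65, the cell wall gene TIR2 at -1.86 ± 0.58 and the galactose permease gene GAL2 at -1.87 ± 0.64, each at an adjusted p of 0.63. With simulated changes this promoter test recovered 0 of 200 genes at a log2 size of 1 and 75 at 2. It therefore does not show that promoters were unchanged. The array calls were not stable, being 0 without untreated 4 or 12 min, 287 without untreated 8 min, 4, 79 and 10 without treated 6, 8 and 16 min, and 0 without the libraries of over 25% empty bins. They were 631 against the other reference, 27 with 40 bp bins, 354 with depth as a covariate, 3 at matched times and 0 as nascent minus total. One culture stands behind each arm.

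Chd1 is a remodeller that spaces nucleosomes. Against wt courses 1 and 2, 0 of 5364 promoters passed in chd1 nascent chromatin (limma, 303 with an unadjusted p under 0.05). The largest list values were PFK2 of glycolysis at 1.48 ± 0.41 and the pheromone kinase gene FUS3 at 1.54 ± 0.50 (log2, SE, adjusted p = 0.79 for both), and the median of all genes was 0.26. CHD1 itself was at 2.24 ± 0.44 (adjusted p = 0.058), the gene body in its denominator being deleted. It was the only gene of 5368 whose array similarity passed (-1.16 ± 0.20, limma adjusted p = 0.016), and RPL13A was at -0.86 ± 0.27 (adjusted p = 0.88). The phasing amplitude was 0.274 ± 0.0434 against 0.432 ± 0.0401 (SD) in wt course 2, lower at 7 of 7 times (exact permutation p = 0.0156, the smallest possible, adjusted p = 0.0781). The single chd1 total library had an amplitude of 0.113, an array similarity of 0.632 and its +1 nucleosome at 67.5 bp, against means of 0.431, 0.845 and 50.2 bp in wt total libraries, without a test. Calls depended on the control, with 1618 promoters and 1047 arrays without wt course 2 and 4 and 12 without wt course 1. These fits also drop the course block, so against the planned counts the control and the block changed together.

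Hir1 belongs to the HIR complex, a chaperone of histones H3 and H4 outside replication and a repressor of histone genes. In hir1 nascent chromatin the promoters of the 6 HIR-regulated histone genes had a median difference of -0.37 (mean -0.49) while the median gene was at 0.27. Camera set these genes below others with an adjusted p of 3.2e-06, and of 0.025 with an estimated correlation. The list of 8 core histone genes (median -0.14, mean -0.23) kept its call (camera adjusted p of 0.00038, and 0.032 with an estimated correlation). It shares members with the HIR-regulated list, so this is not a separate result. The list tests ran on serial libraries of hir1 courses 1 and 2 against wt courses 1 and 2. They were neither simulated for this fit nor rerun without a course, and the like fit of chd1 gave many false calls on simulated data. They therefore cannot separate the strain from a course effect that histone genes share. No member passed alone in the test over all genes (limma, 445 genes with an unadjusted p under 0.05), and 1 was lower in each list adjusted over the list alone. HHF1 was at -1.36 ± 0.44 (log2, SE, lower at 11 of 13 matched times, limma adjusted p = 0.54), HHT2 at -0.75 ± 0.36, HTA1 at -0.60 ± 0.31 and HTB2 at 0.69 ± 0.40, with reads possibly shared between paired histone genes. Fry, which asks whether a set moves one way on balance, gave an adjusted p of 0.10 for the 6 genes. Ribosome biogenesis (median 0.34), G2/M (0.37) and proteasome genes (0.39) moved up on balance (fry adjusted p = 0.0255 for each), as did the median of all genes. Camera calls of ribosomal protein genes and of highly transcribed genes, a list that holds them, had adjusted p of 0.00052 and 0.00038. Both were lost with an estimated correlation (camera adjusted p = 0.26 for both). The 1 promoter called was HIR1 (3.94 ± 0.33, limma adjusted p = 1.6e-12), whose body is deleted, and PRM5 was at 1.54 ± 0.40 (adjusted p = 0.54). Array similarity was lower at AHT1 (-1.01 ± 0.20), MET18 (-0.91 ± 0.14) and the nucleoporin gene NUP159 (-0.84 ± 0.15), with limma adjusted p of 0.024, 0.0011 and 0.0079, and PRM5 was at -0.97 ± 0.21 (0.084). Without wt course 2, 681 promoters and 369 arrays were called, and without either hir1 course 0 arrays (limma, 166 with an unadjusted p under 0.05 over both courses).

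The 2 hir1 courses differed at the level of libraries. Against wt course 2 the amplitude of hir1 course 2 was lower by -0.208 ± 0.0498 (SD, 7 of 7 times, adjusted exact permutation p = 0.0391) and its +1 nucleosome lay 7.84 ± 4.21 bp further downstream (7 of 7, adjusted exact permutation p = 0.0391). In hir1 course 1 the amplitude differed by -0.0475 ± 0.0563 (5 of 6 lower) and the NDR ratio was higher by 0.0486 ± 0.0136 (6 of 6, exact permutation p = 0.0312, adjusted p = 0.156).

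**Figure D4:**
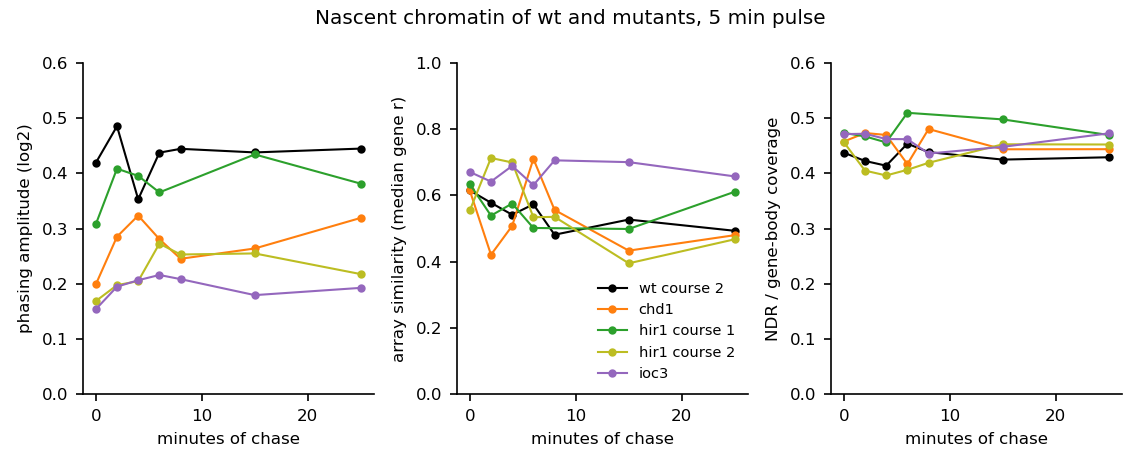
Phasing amplitude (log2), array similarity (median correlation over genes) and NDR signal relative to the gene body of nascent libraries against minutes of chase, 1 point per library, for wt course 2 and the mutant courses with a 5 min pulse. The ioc3 amplitude averages 0.193 and that of wt course 2 0.432, while the ioc3 array similarity averages 0.671 against 0.544.

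Ioc3 belongs to the Isw1a remodeller. In ioc3 nascent chromatin 432 of 5352 promoters were higher and 105 lower than in wt course 2 at the same 7 times (median of all genes 0.17). The myosin gene MYO1 was higher by 1.46 ± 0.23 (log2, SE, 7 of 7 times, limma adjusted p = 0.00026), IPK1 by 1.35 ± 0.21, the replication protein A subunit gene RFA3 by 1.30 ± 0.22 and YCL041C by 1.25 ± 0.19. The chitinase gene CTS1 (-1.51 ± 0.21), YML083C (-1.51 ± 0.22), the sulfite reductase gene MET5 (-1.47 ± 0.22), DCV1 (-1.23 ± 0.20) and FPR2 (-1.16 ± 0.23) were lower. Ribosomal protein genes gave 15 higher and 0 lower of 127 (17 and 0 adjusted over the list alone), with RPL19A at 1.22 ± 0.29 and RPL42A at 1.00 ± 0.26 (each higher at 5 of 7 times) and RPL35A at 0.96 ± 0.23. G1/S genes gave 5 higher of 35 (7 adjusted over the list alone), including the S phase cyclin gene CLB6 (1.19 ± 0.20). Both lists moved up on balance (fry adjusted p of 0.0108 and 0.0061), and neither passed camera. PFK1 was at 0.94 ± 0.22, HHT2 at 0.84 ± 0.21 (6 of 7) with reads possibly shared with HHT1, the sporulation gene SPS100 at -0.84 ± 0.18 and STE2 at -0.70 ± 0.17. The deleted IOC3 gave 3.95 ± 0.20. NDR calls were 313, 282, 356 and 332 without the 0, 2, 8 and 15 min times and 840 with a pseudocount of 0.5.

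Arrays of ioc3 nascent genes were more like the reference than those of wt course 2, with 1265 of 5356 genes higher and 85 lower (median of all genes 0.19). They were not more so than those of wt course 1, whose nascent libraries averaged an array similarity of 0.684 against 0.671 in ioc3, at other times. COX14 (1.47 ± 0.14, Fisher z, SE, 7 of 7 times, limma adjusted p = 3.3e-06), RFS1 (1.40 ± 0.15), the translocon gene SBH1 (1.39 ± 0.16), SMA2 (1.36 ± 0.14) and RBD2 (1.29 ± 0.13) were higher. MEF1 (-0.65 ± 0.13), the spindle checkpoint gene BUB3 (-0.64 ± 0.13), DOP1 (-0.58 ± 0.14) and NOP2 (-0.57 ± 0.16) were lower, and RAD50, at -0.66, turned to 0.0046 against the other reference. Ribosomal protein genes gave 51 higher and 1 lower of 127 (59 and 1 adjusted over the list alone), led by RPL34B (1.21 ± 0.14) and RPP2B (1.09 ± 0.19). Their camera adjusted p of 0.0081 was lost with an estimated correlation (adjusted p = 0.69). Glycolysis genes gave 9 higher of 17, the same adjusted over the list alone, including ENO2 (0.79 ± 0.15), and the cohesin factor gene PDS5 (0.95 ± 0.14), FUS3 (0.78 ± 0.14), HSP10 (0.76 ± 0.14) and HHF2 (0.52 ± 0.14, reads possibly shared with HHF1) were higher, while IOC3 was lower (-0.33 ± 0.12). Without the 8 min time 895 genes were called, with depth as a covariate 316 and against the other reference 720. By library the similarity was 0.671 ± 0.0291 against 0.544 ± 0.0481 (SD, 7 of 7 times higher, adjusted exact permutation p = 0.0260), the +1 nucleosome lay 7.46 ± 2.69 bp further downstream (7 of 7) and the NDR ratio was higher by 0.0290 ± 0.0203 (6 of 7, adjusted exact permutation p = 0.0391, and 0.0586 with the median over genes). The amplitude was 0.193 ± 0.0211 against 0.432 ± 0.0401 (7 of 7 lower, adjusted exact permutation p = 0.0260). The single ioc3 total library had an amplitude of 0.168, an array similarity of 0.620 and its +1 nucleosome at 62.9 bp. With 1 course per strain in this comparison, strain and course cannot be told apart.

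**Figure D5:**
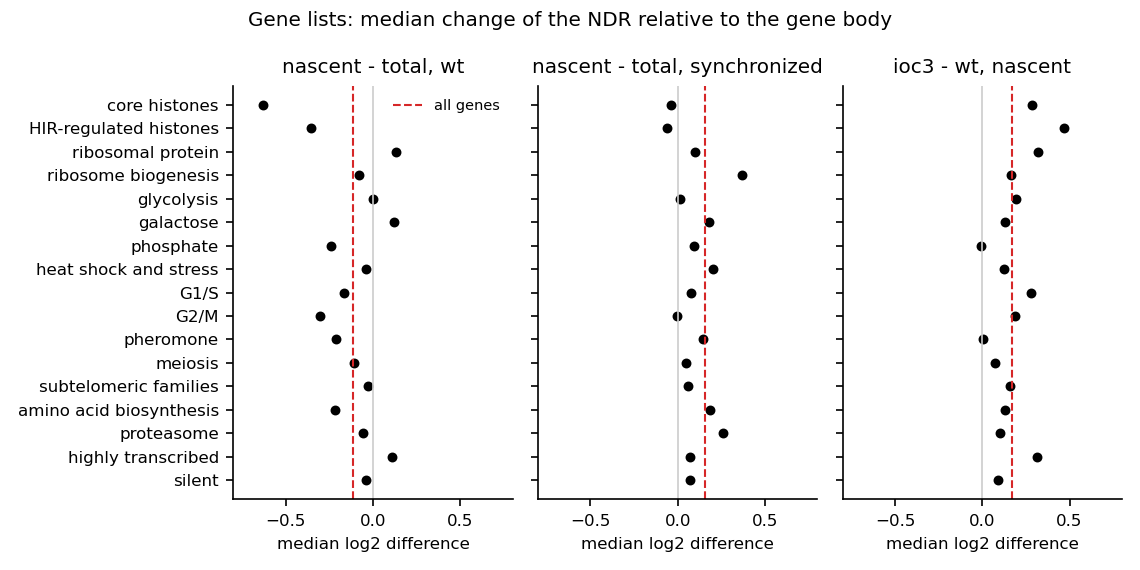
Median log2 difference of NDR signal over gene body for 17 gene lists (points), with the median of all genes as a dashed line, for nascent minus total chromatin of wt course 1 and of synchronized cells and for ioc3 minus wt course 2. Core histone genes lie at -0.63 in the first panel, ribosome biogenesis genes at 0.37 in the second and ribosomal protein genes at 0.32 in the third.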

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

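The tests of noise between strands, of maturation over time, of preparation, of a similar sequence and of thinning without thiolutin were chosen after the results were seen. Single libraries stood apart in 8 of 71 tested groups of 4 to 10 libraries, where chance gives about 1 in 20 groups.

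Array similarity was 0.538 in the hir1 course 2 total library at 15 min (others 0.717 to 0.817), which had 3.67 reads per bin. It was 0.529 in the wt 20 min pulse course 2 nascent library at 8 min (others 0.622 to 0.659). The wt course 1 nascent library at 12 min had a repeat length of 162.6 bp (others 164.4 to 164.7) and its +1 nucleosome at 58.1 bp (others 49.7 to 50.2), and the total library of that time had its +1 nucleosome at 52.01 bp (others 48.2 to 48.7). The thiolutin nascent library at 6 min had its +1 nucleosome at 44.5 bp (others 52.1 to 52.9). HIR1 coverage was 0.00704 in the hir1 course 2 nascent library at 0 min (others 0 to 0.00167) and 0.0503 in its total library at 6 min (others 0 to 0.00184).

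The nascent minus total difference of the +1 position was 2.60 bp in wt, positive in every pair, and negative in every pair of hir1 course 1 (-12.2), hir1 course 2 (-8.15) and the synchronized course (-9.19). In wt it was 6.12 bp at 12 min and 1.00 to 1.66 bp at the other times. Peak positions of the synchronized course are poorly defined, its mean phasing amplitude being 0.0492 (nascent) and 0.0212 (total). A permutation of the differences between courses gave p = 0.0028 for hir1 against wt (adjusted p = 0.0587) and p = 0.0286 for the synchronized course (adjusted p = 0.218). The libraries labelled hir1 course 1 total carried HIR1.

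The lower array similarity of nascent chromatin was weighed first. Total libraries were thinned to the depth of their nascent partner in the 12 of 19 pairs where the total was deeper, and left as they were in the others. Nascent libraries still fell below them, by a difference of -0.157 (lower in 19 of 19 pairs), which argues against fewer reads as the whole cause. The largest differences were those of thiolutin at 6 min (-0.531) and 8 min (-0.295), and without the thiolutin pairs the mean was -0.122 (lower in 16 of 16). Thinning matched reads per bin and not the number of distinct molecules. After correction for the agreement between strands the difference was -0.101 (18 of 19 lower), which argues against noise as the whole cause. For maturation over the minutes sampled, the mean r of the corrected similarity with time was -0.0726 (2 of 7 courses rising, permutation p = 0.650), so it stays open. A difference of newly copied chromatin itself stays open. The reference for similarity is itself a total library, taken without the capture that made the nascent libraries. None of these tests can therefore separate newly copied chromatin from that capture. Phasing amplitude, the other measure of array order, was not lower in nascent chromatin (0.311 against 0.260, and a difference of -0.00204 in wt).

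The lower phasing amplitude of chd1, hir1 course 2 and ioc3 nascent chromatin against wt course 2 was weighed second. The mutant libraries were deeper, by at least 1.44 times on average, which argues against low depth. The 2 courses of hir1, of 1 strain, differed by -0.163 at matched times (6 of 6 lower, exact p = 0.0312), so the preparation of a course, such as the extent of digestion, may produce a difference as large as that of chd1 (-0.158). It falls short of that of ioc3 (-0.239), and the 2 wt courses with a 5 min pulse were alike (0.448 and 0.432). Other wt nascent courses lay near or below the ioc3 mean of 0.193, at 0.194 and 0.189 (20 min pulse) and 0.0492 (synchronized). Pulse or synchrony differed there as well. The gap between the hir1 courses is therefore no upper bound on what preparation can produce, and it does not set ioc3 apart. For hir1 course 2 (-0.208) the comparison decides nothing, since both values rest on that same course. The other course of the strain, hir1 course 1, had a mean amplitude of 0.382, nearer to wt course 2. The strains, as the biological explanation, stay open.

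The HIR1 reads in the libraries labelled hir1 course 1 total were weighed last. Reads lay over 100% of the HIR1 body bins in each of the 4, as a sample carrying HIR1 would give. The other 19 hir1 libraries reached at most 0.0503, which argues against a similar sequence elsewhere. The libraries stood at 15.6, 8.33, 10.9 and 33.7% of the level of libraries with HIR1 at 2, 8, 15 and 25 min, so a mixture with another sample is a candidate explanation. The coverage of CHD1 and IOC3 left in the chd1 and ioc3 libraries was not examined in this way. No biological explanation was tested.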

How the results depend on the processing

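The alternatives with 40 bp bins, depth as a covariate, corrected similarity, leaving out libraries of the thiolutin comparison, whole courses or pulse courses, and leaving out libraries of over 25% empty bins were chosen after the data were seen, and the others before. The causes of the changes were not tested. Bins of 10 bp were not run, since the tables hold 20 bp bins, and smoothing over 30 bp was not applied.

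Of the 98 values that 20 counts of genes took under alternatives other than leaving out a library, 57 stayed within 1.5 times and 41 moved, and of 84 that left out a library 41 stayed and 43 moved. Of 144 such values of 90 library results 121 were the same, 9 weaker and 14 reversed, and of 45 that left out a library or course 37, 6 and 2. Of 902 values of 194 named genes 735 were the same, 145 weaker, 13 stronger and 9 reversed, and of 890 that left out a library 704, 175, 11 and 0.

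With a pseudocount of 0.5, NDR calls were 534 (wt nascent against total), 0 (thiolutin, limma, where 568 genes had an unadjusted p under 0.05 in the planned analysis), 476 (hir1 course 2), 4 (wt slopes) and 840 (ioc3). With the fixed NDR window they were 2 (thiolutin nascent against total) and 1 (chd1). Without the filter on low genes they were 165 (wt), 0 (thiolutin), 238 (hir1 course 1) and 37 (hir1 course 2).

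Without the replicate block, NDR calls of nascent against total were 63 (wt), 0 (thiolutin) and 373 (synchronized), those of chd1 8 and of hir1 321. Array calls without the block were 1048 (hir1 course 2), 15 (synchronized), 32 (chd1) and 10 (hir1). With wt course 2 alone and the time point as replicate block, NDR calls were 4 (chd1) and 20 (hir1) and array calls 7 and 9. With matched times as replicate block, thiolutin against untreated gave 3 NDR and 3 array calls. For ioc3 and wt course 2, which share only the time number, the correlation of the libraries of a time ran from -0.0462 to 0.135 for NDR values (best with the own time in 3 of 7) and from -0.108 to 0.0713 for arrays (2 of 7), so the time block takes up little.

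Against the reference mean, array calls were 5272 (wt), 631 (thiolutin against untreated), 5 (hir1) and 720 (ioc3). The wt count is in part built in, since the totals compared are those that make up the reference mean. With 40 bp bins they were 16 (synchronized) and 27 (thiolutin against untreated). With depth as a covariate they were 313 (wt), 1496 (thiolutin), 18 (hir1 course 1), 2430 (hir1 course 2), 0 (synchronized), 354 (thiolutin against untreated) and 316 (ioc3). As nascent minus total, and without libraries of over 25% empty bins, thiolutin against untreated gave 0 (limma, 1536 at an unadjusted p under 0.05 in the planned analysis).

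Leaving out 1 pair or time, NDR calls ran from 27 (16 min) to 340 (8 min) in wt, 6 (8 min) to 62 (6 min) with thiolutin, 0 (25 min) to 341 (2 min) in hir1 course 1, 7 (6 min) to 294 (15 min) in hir1 course 2, 510 (40 min) to 994 (32 min) in synchronized cells and 282 (2 min) to 506 (4 min) for ioc3. Array calls ran from 1461 (16 min) to 2187 (4 min), 1345 (8 min) to 2657 (25 min), 0 (2 min) to 1257 (25 min), 736 (6 min) to 2026 (4 min), 0 (40 min) to 94 (32 min) and 895 (8 min) to 1268 (2 min) in the same order. For thiolutin against untreated the array calls ran from 0 (untreated 4 min) to 287 (untreated 8 min). Leaving out a course, they ran from 4 (wt course 1) to 1618 (wt course 2) for chd1 NDR, 12 to 1047 for chd1 arrays, 1 to 681 for hir1 NDR, and 0 (either hir1 course) to 369 (wt course 2) for hir1 arrays. The chd1 fits without a wt course also drop the course block. Counts of 0 are from limma.

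With the median over genes, each gene scaled to its own mean, the pooled nascent minus total NDR ratio was 0.0292 (adjusted p = 0.101) and the repeat 0.999 bp, both past no threshold. It reversed the wt NDR ratio (0.000288), the wt amplitude (0.0152), the thiolutin NDR ratio (-0.101) and +1 position (0.775), and the synchronized repeat (-2.33). It reversed relations with time, given as r, of the NDR ratio in wt 20 min pulse course 2 (-0.531), hir1 course 1 (-0.418) and hir1 course 2 (-0.448), of the repeat in wt 20 min pulse course 2 (-0.163) and of the +1 position in wt 5 min pulse course 2 (-0.110), wt 20 min pulse course 1 (-0.0898) and hir1 course 1 (-0.362). Against wt the NDR ratio of hir1 course 2 reversed (0.00216) and that of ioc3 lost its call (0.0366). Landmarks of each library's own profile reversed the wt amplitude (0.00325).

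Leaving out a course, the pooled amplitude difference ran from 0.0184 (without hir1 course 1, exact p = 0.310) to 0.0792 (without hir1 course 2), with an exact p of 0.107 without thiolutin and 0.0693 without the synchronized course. The pooled repeat difference ran from 0.693 (without hir1 course 2, exact p = 0.0747) to 1.97 (without wt). For pulse length the NDR ratio ran from 0.0431 to 0.146, the +1 position from 3.56 to 7.04 with the NDR ratio and the +1 position no longer past the threshold without 5 min course 2 (exact p = 0.0545 and 0.127), and array similarity from -0.0737 to 0.0357, positive also without 5 min course 1 (0.0207).

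Of 174 named values past the threshold 97 fell short of it under at least 1 alternative and 9 changed sign, all against the reference mean: YCR064C (-1.11), INO1 (-0.95), YBL028C (-1.06), LSB1 (-0.93), FRM2 (-0.74), YCR087C-A (-0.92), CIN2 (-0.029), FAA1 (-0.86) and RAD50 (0.0046). For YCR064C, INO1, YBL028C, LSB1 and FRM2, of the wt comparison, the change is in part built in, since the totals compared make up that mean. Of the named values not past the threshold 0 changed sign.

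Depth limited the hir1 course 2 total library at 15 min (3.67 reads per bin). The thiolutin nascent libraries had 14.6 to 48.1% empty bins at 19.1 to 63.8 reads per bin, no shallower than wt course 1 nascent (12.2 to 42.2).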

Other observations

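The corrected similarity, the strand agreement and the absolute origin distance were added after the data were seen.

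Genes of SAGA and TFIID promoters differed little in the wt nascent minus total NDR values, with medians of -0.12 (591 genes) and -0.11 (4447 genes). The share of nascent signal in synchronized cells had a Spearman rho of -0.704, -0.562 and -0.552 with the absolute distance to the nearest origin at 32, 40 and 55 min (6181 genes). In ioc3 nascent libraries the corrected similarity exceeded that of wt course 2 by 0.0841 ± 0.0458 (7 of 7 times), which bears on the similarity pattern after strand noise. Its mean was 0.770 in ioc3 and 0.686 in wt course 2, but 0.795 in wt course 1 nascent libraries. The agreement between strands was 0.521 in nascent and 0.805 in total libraries of the 19 pairs.

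Other splits of the same libraries were counted for each comparison of single genes. The splits were too few for a share under 0.05 in wt (1 of 8 as large, NDR 345 and highest other 0, arrays 2292 and 0), thiolutin (1 of 4, 37 and 1, 3269 and 0), hir1 course 1 (1 of 4, 537 and 0, 1682 and 0) and the synchronized course (1 of 4, 1180 and 0, 33 and 0). A chance sorting of these libraries within their pairs is excluded, though chance between cultures is not tested, for hir1 course 2 (1 of 32, NDR 193 and highest other 1, arrays 1582 and 607) and ioc3 (1 of 64, NDR 537 and 31, arrays 1350 and 78). The hir1 course 2 NDR count was 7 and 22 without the 6 and 8 min pairs. For the arrays of thiolutin against untreated 1 of 35 splits was as large (122 and highest other 111), and chance is not taken as excluded, since 0 genes were called without untreated 4 or 12 min (limma, 1536 with an unadjusted p under 0.05 over all libraries). Chance is also not excluded for the NDR of thiolutin against untreated (35 of 35, 0 and 0, limma, 382 at an unadjusted p under 0.05) and of chd1 (100 of 100, 0 and 15, limma, 303 at an unadjusted p under 0.05). For hir1 NDR and chd1 arrays the 1 gene called is the deleted HIR1 or CHD1, so the counts of 4 of 100 (1 and highest other 1) and 6 of 100 (1 and 289) decide nothing. For hir1 arrays 3 of 100 splits were as large (3 and highest other 71), and chance is not taken as excluded. Why splits called 289 and 71 arrays, several times the real count, was not tested. On simulated data the chd1 array fit also gave 112 false calls.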
